A study of Homo sapiens with 10 samples.

How the data were processed

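CUT&Tag was run on HEK293T cells with antibodies to IgG, OGT and Dot1L in untreated cells and to OGT after 72 h of control or Dot1L siRNA, with 2 libraries per group and 10 in all. Per the labels' protocols, cells were held on concanavalin A beads and a protein A/G transposome was directed by the antibody. Per the submitters' processing notes, CASAVA 1.4, Bowtie 1.1.2, bedtools, SEACR 1.3 and deepTools were used, on the hg38 build; the role of each tool and whether duplicate fragments were removed are not given in the sources used here. The deposited files hold whole-number fragment counts per 500 bp bin, list only bins with at least 1 fragment, and carry no normalization, as their values show.

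Libraries were grouped by the labels. Only fragments on chromosomes 1 to 22, X and Y were used, and depth was their total per library; mitochondrial fragments were left out. Counts were divided by that total to give CPM, and no spike-in was used here, so CPM are shares. Gene positions and names came from RefSeq genes of GRCh38.p14, the build of the files, for 20037 protein-coding genes. The tests had been planned on promoters and gene bodies, but the table used gives no strand. Gene-end windows, summing bins within 1 kb of either annotated end, took the place of promoters, and interiors, at least 1 kb inside both ends of genes of 3 kb or more, the place of gene bodies. This departs from the plan: in 60.6% of genes 1 end held at least 3 times the fragments of the other, and 34.8% share part of their window with another gene, so a call may belong to the neighbour named beside it.

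Counts of the 8 antibody libraries were fitted together with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood with group means, 4 residual degrees of freedom, library size set to total nuclear fragments, no composition factor and filterByExpr. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The comparisons were Dot1L siRNA against control siRNA at gene ends, in interiors and in OGT-enriched regions, OGT against Dot1L at gene ends, and control siRNA against untreated OGT at gene ends. IgG was too shallow to fit and entered as background in the shares of fragments. Enriched regions were bins with at least 3 fragments and a Poisson adjusted p under 0.01 against the larger of the genome mean and the mean over 100 kb around them, in both libraries of a group, with bins at most 1 apart merged. Gene-end shares carry Wilson 95% intervals and exact two-sided permutation tests of 2 against 2 libraries. Correlations across genes used log2(CPM + 1).

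Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. The 26 lists were cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, replication-dependent histones, DNA replication, mitosis, and the hexosamine pathway. Others were DOT1L with the super elongation complex and partners, OGT chromatin partners, H2B ubiquitination, proteasome, RNA splicing, aminoacyl-tRNA synthetases, heat shock and unfolded protein response, immediate early genes, p53 targets, and interferon response. The rest were HOX genes, developmental transcription factors, KRAB-type zinc finger genes, olfactory receptors, keratins, and blood cell, liver, kidney tubule and neuronal markers. The zinc finger list was taken by ZNF symbol and not by the presence of a KRAB domain. The lists, tests, main scaling, other settings compared and rule for named genes were fixed before the data were examined. The rule names called genes with both libraries of 1 group above both of the other, the 10 largest rises and 10 largest falls. It adds the 10 highest levels of each antibody with fewer than 3 IgG fragments, and up to 3 members of each list by smallest p. DOT1L, OGT, OGA and HCFC1 are always named, and the 5 largest regional changes each way. The use of gene ends in place of promoters, the named interior genes and the comparisons by gene length were chosen after seeing the data.

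A group without a fragment was given a floor of 3 fragments over both libraries, from which "at least" folds were computed, and groups with 1 to 3 fragments have a ratio with its exact counting interval. Intervals and floors cover counting error only. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. In the gene-end, interior and region fits edgeR estimated infinite prior degrees of freedom, so the spread was pooled over features. A gene's own spread between its 2 libraries therefore did not enter its edgeR p-value, and a gene with a large SD could be called. Within each antibody group, single-fragment bins were shared between the 2 libraries more often than neighbouring bins, so fragments common to both are not excluded, and with them the p-values would be too small.

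The scripts were tested on simulated counts with 200 changed features. At gene ends 4-fold rises after Dot1L siRNA were recovered in 80% and 4-fold falls in 8.16% of cases, with 3 of 10775 unchanged genes called; for 2-fold changes the shares were 12.5% and 4%. Between OGT and Dot1L the 4-fold shares were 100% and 75.5%, in interiors 64% and 12.2%, in regions 74% and 23.3%, and between control siRNA and untreated cells 91.7% and 28.6%. Falls after Dot1L siRNA are thus rarely detectable at this depth. A simulated list of 70 genes lowered 2-fold was found by camera in the siRNA contrast, and 4 of 200 unchanged lists had p under 0.05. The simulated genes were drawn independently, so this check does not cover lists whose members vary together.

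The alternatives were TMM factors over the tested features or over 10 kb bins, DESeq2 1.42.0, no filter, and only the groups compared. Others were the replicate number as a block, each library left out, windows of 500 bp or 2.5 kb, bins with an IgG fragment left out, libraries thinned to one total, stricter regions, other overlap rules and an estimated correlation. Added after seeing the data were the gene end with more Dot1L fragments, each bin counted once in the gene tests, shares at one depth with each bin counted once, the overlap without IgG bins and the estimated correlation for the Dot1L-enriched genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the counting and figures.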

Results

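HEK293T cells, an immortalised human embryonic kidney line, were profiled by CUT&Tag, in which an antibody bound to chromatin directs a transposase to cut and tag the DNA beside it. The 10 libraries form 5 groups of 2. In untreated cells the antibodies were IgG, which serves as the background control, an antibody to OGT, the enzyme that attaches O-linked N-acetylglucosamine to nuclear and cytoplasmic proteins, and an antibody to Dot1L, the methyltransferase of histone H3 lysine 79. The OGT antibody was also used on cells 72 h after a control siRNA or an siRNA against Dot1L. The series asks what Dot1L contributes to the O-GlcNAc modification of histones, and its design sets OGT beside Dot1L in untreated cells and OGT with Dot1L siRNA against OGT with control siRNA.

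Depth differed widely between groups. Fragments on chromosomes 1 to 22, X and Y numbered 2553359 and 6109187 in the OGT libraries of untreated cells, 1589621 and 3843689 in the Dot1L libraries, 518717 and 1197265 after control siRNA, and 62307 and 151683 after Dot1L siRNA. The IgG libraries held 1554 and 5060. The control siRNA group was thus 8.02 times as deep on average as the Dot1L siRNA group, and among the antibody groups a single fragment weighs most in the latter. Levels below are fragments per 1000000 nuclear fragments (CPM), given as mean ± SD with n = 2 libraries per group. They are shares of a library, so a change means a change relative to the other chromatin in that library, and no absolute amount of bound OGT can be read from them. A gene's level is summed over the 500 bp bins within 1 kb of either annotated end of the gene, called its gene ends here, because no strand was available to separate the transcription start from the other end.

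The first comparison asks how much of each library lies at the ends of protein-coding genes, which hold 2.36% of all bins. Gene ends took 43.4% ± 0.239 of OGT fragments after control siRNA and 30.4% ± 0.234 after Dot1L siRNA, a ratio of 0.701, which ran from 0.694 to 0.708 over the 4 pairings of single libraries. In untreated cells the share was 8.83% ± 0.0730 for OGT and 9.33% ± 0.0733 for Dot1L, so OGT after control siRNA had a share 4.92 times that of OGT in untreated cells. IgG, the background measured in the same way, had 11.8% ± 0.320, above both antibodies in untreated cells and below both siRNA groups. In each of these comparisons the libraries of one group lay apart from those of the other, and the exact permutation test of 2 against 2 libraries gave a two-sided p = 0.333, the smallest it can give. The IgG shares rest on 180 of 1554 and 609 of 5060 fragments, with 95% Wilson intervals of 10.1 to 13.3% and 11.2 to 13.0%. With each bin counted once however many fragments it held, the ratio of Dot1L siRNA to control siRNA turned to 1.65, and with the libraries also thinned to one depth it was 0.732.

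**Figure D1:**
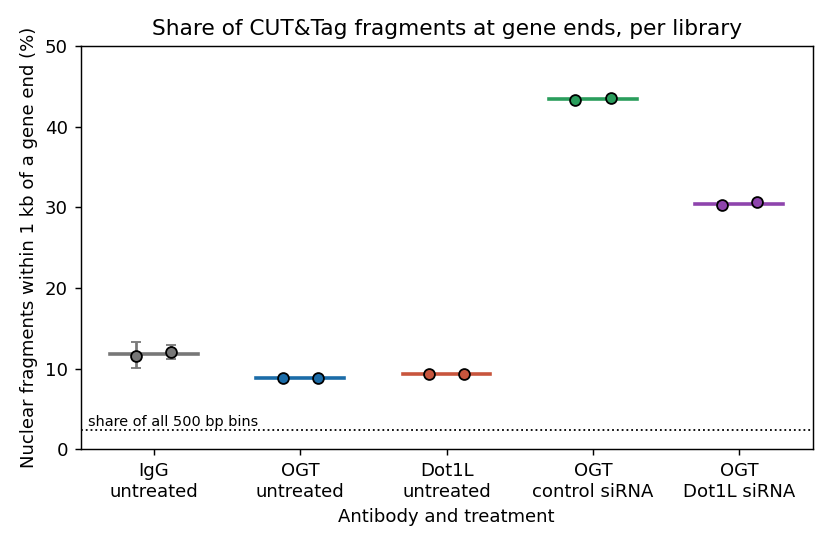
Percent of nuclear fragments within 1 kb of an annotated end of a protein-coding gene (vertical axis) for each of the 10 libraries, by antibody and treatment (horizontal axis). Points are libraries with 95% Wilson intervals, horizontal bars are group means, and the dotted line is the 2.36% of all bins that lie there; the control siRNA libraries stand at 43.4% on average, the Dot1L siRNA libraries at 30.4%, and OGT, Dot1L and IgG in untreated cells between 8.83% and 11.8%.

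Around the ends of 11011 protein-coding genes of at least 20 kb, the mean level at the gene end itself was 0.907 and 0.911 CPM per bin in the 2 OGT libraries of untreated cells and 0.943 and 0.949 in the 2 Dot1L libraries. The shallow IgG libraries had 1.26 and 1.22, above both antibodies in untreated cells. It was 5.30 CPM per bin in both control siRNA libraries and 3.53 and 3.56 after Dot1L siRNA. At 10 kb inside the gene the 8 antibody libraries lay between 0.163 and 0.208 CPM per bin.

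**Figure D2:**
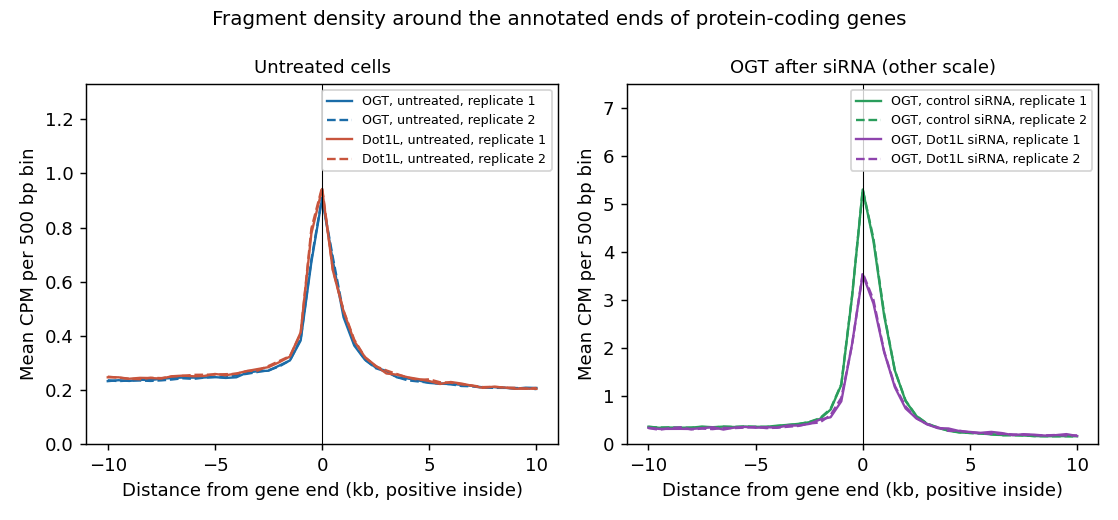
Mean CPM per 500 bp bin (vertical axis) against distance from an annotated gene end in kb, positive inside the gene (horizontal axis), for OGT and Dot1L in untreated cells (left, IgG not drawn) and for OGT after control or Dot1L siRNA (right, on another scale). Solid and dashed lines are replicates 1 and 2, and at the gene end the control siRNA libraries reach 5.30 and the Dot1L siRNA libraries 3.53 and 3.56 CPM per bin.

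The next comparison asks whether OGT and Dot1L sit on the same chromatin. Among genes with fewer than 3 IgG fragments, taking 1 gene per shared window, 5 of the 10 highest gene-end levels were at the same genes with both antibodies. AMPD3, at 32.9 ± 11.6 CPM with OGT, was left out for its 3 IgG fragments. The window of MYL11 (chromosome 16, 30370934 to 30377991), a myosin light chain gene whose ends it shares with SEPTIN1, TBC1D10B and ZNF48, stood highest in both, at 56.9 ± 3.41 CPM with OGT and 85.2 ± 4.96 with Dot1L. SHC1, a signalling adaptor that shares its window with CKS1B and PYGO2, had 43.3 ± 0.807 and 54.2 ± 4.62 CPM. FBRS had 41.8 ± 4.81 and 48.9 ± 5.13, CRYZL1, beside the replication fork gene DONSON and ITSN1, 34.4 ± 2.09 and 49.0 ± 0.111, and U2AF2, which recognises the 3′ splice site and shares its window with EPN1, 34.3 ± 0.295 and 55.5 ± 8.28 CPM. These are the 5 in common. The other members of the OGT list were RNF40, the ubiquitin ligase of histone H2B (38.2 ± 2.44 CPM), PRRT2 beside MAZ and PAGR1 (34.9 ± 6.18), ACIN1 beside C14orf119 and CDH24 (34.3 ± 0.329), EXOC8 beside SPRTN (34.0 ± 0.642) and DNAI4 beside MIER1 (31.3 ± 5.09). The other members of the Dot1L list were USP1, the deubiquitinase of PCNA (56.4 ± 0.298 CPM), FBXL19, a CpG island binding protein beside ORAI3 (55.6 ± 9.27). Further members were the chaperonin subunit CCT3 beside TSACC (50.7 ± 2.15), the deubiquitinase USP5 beside CDCA3 and TPI1 (50.1 ± 2.07) and the repressor CIC beside PAFAH1B3 (49.3 ± 3.18).

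Enriched regions called in both replicates numbered 6717 for OGT, of which 71.9% touched a gene end, and 5984 for Dot1L, of which 62.6% did. Of the OGT regions 2817, or 41.9%, overlapped a Dot1L region by at least 1 bin. The 3401 bins called for both compare with 18.4 for independent sets of the same size, a ratio of 185. Independent sets are spread evenly over all bins with a fragment, so the ratio does not allow for sites that every library favours. The other pairs of antibody groups had ratios from 108 (Dot1L with OGT after control siRNA) to 281 (Dot1L with OGT after Dot1L siRNA). A high ratio is thus not particular to OGT with Dot1L in untreated cells. For that pair the ratio within gene ends was 9.68, where 2760 bins were shared, and outside them 358, where 641 were shared. No region was called in both IgG libraries, which were too shallow to show whether the shared sites are also favoured without a specific antibody. Across 20037 genes, which are not independent replicates, mean gene-end levels of OGT and Dot1L had a Spearman rho of 0.893 and a Pearson r of 0.894. Between single libraries rho was 0.825 to 0.888 for OGT with Dot1L, beside 0.926 between the 2 OGT libraries and 0.905 between the 2 Dot1L libraries. Mean levels of OGT in untreated cells and OGT after control siRNA had a rho of 0.905. Leaving out 1 library, so that the other of its group alone makes the calls, changed these values. Without OGT replicate 1 there were 23025 OGT regions, 8699 of them at a gene end, and an overlap of 19.2%, and the ratio was 77.2, or 5.92 within and 98.6 outside gene ends. Without Dot1L replicate 1 there were 37013 Dot1L regions, 7993 of them at a gene end, the overlap was 69.9%, and the ratio was 53.4, or 6.09 within and 60.7 outside gene ends. Without Dot1L replicate 2 there were 10305 Dot1L regions, 4267 of them at a gene end, and the ratio was 119, or 154 outside gene ends, and without OGT replicate 2 it was 183 outside gene ends. With regions called in either library the ratio was 26.9, with stricter regions 377 (15.8 within and 1286 outside gene ends) and with the libraries thinned to one total 436 (18.0 within and 1582 outside).

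Gene by gene, 1468 of 10857 tested genes differed between OGT and Dot1L in untreated cells (edgeR, adjusted p under 0.05), 591 higher with OGT and 877 higher with Dot1L. The largest differences toward OGT were at DCUN1D2 (window shared with SLC9D1), a cullin neddylation factor, with 4.04 ± 0.384 CPM and no Dot1L fragment, at least 7.11-fold higher, at AKR1E2, at least 3.76-fold higher, and at DYNLT2 (window shared with ERMARD and PHF10), at least 2.30-fold higher. NUAK1, an AMPK-related kinase, held 48 OGT and 2 Dot1L fragments, a ratio of 15.1 (95% counting interval 3.95 to 128). Spermidine synthase, SRM, held 64 and 3 fragments, a ratio of 13.4 (95% counting interval 4.38 to 66.6), and TAF4, a subunit of TFIID, 20 and 1, a ratio of 12.5 (95% counting interval 2.01 to 519.9). ANKH, a membrane transporter (44 and 2 fragments), RBPMS, an RNA-binding protein (24 and 1), KLHL17 beside NOC2L and PLEKHN1 (22 and 1) and TOLLIP, a Toll receptor adaptor (38 and 2), completed the 10 largest.

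The largest differences toward Dot1L were at TNFRSF10D, a decoy receptor for the death ligand TRAIL, at 0.409 ± 0.579 CPM with OGT and 2.505 ± 0.873 with Dot1L (log2 difference -2.14, SE 0.758, edgeR adjusted p = 0.0390). WDR7 followed, at 2.60 ± 0.202 and 11.6 ± 2.35 CPM (log2 difference -2.09, SE 0.416, edgeR adjusted p = 7.29e-05). Next came CXXC4 (-2.02), SPOCD1 (-1.97), ZNF160 (-1.95), MTMR8 (-1.93), the caspase gene CASP10 (-1.83), TMT1A beside HIGD1C (-1.82), PACSIN1 (-1.78) and the SUMO protease gene SENP2 (-1.76). Of the genes with the highest levels, USP1 (-1.14), FBXL19 (-0.93), CCT3 (-0.94), CIC (-0.79), U2AF2 (-0.74), USP5 (-0.68), MYL11 (-0.56) and CRYZL1 (-0.49) were also higher with Dot1L. The count of 1468 was 893 without OGT replicate 1, 437 without OGT replicate 2, 924 without Dot1L replicate 1 and 228 without Dot1L replicate 2. DESeq2 called 130 genes, 73 higher with OGT and 57 higher with Dot1L.

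Among the gene lists fixed beforehand, 2 of 26 lay toward Dot1L, cytosolic ribosomal proteins and oxidative phosphorylation (camera with the preset correlation, adjusted p under 0.05). With an estimated correlation 0 lists passed camera (adjusted p = 0.524 for both), with 2 at an unadjusted p under 0.05. Of 74 tested cytosolic ribosomal protein genes 13 were higher with Dot1L and 1 with OGT, with a median log2 difference of -0.36 (camera adjusted p = 0.00648). RPL7, beside RDH10, had 12.4 ± 0.952 CPM with OGT and 23.6 ± 2.28 with Dot1L (-0.93, edgeR adjusted p = 0.00127), and RPS23 3.86 ± 1.02 and 10.6 ± 0.793 (-1.38, edgeR adjusted p = 0.00303). RPL6, whose window PTPN11 shares, was instead higher with OGT at 11.7 ± 2.35 and 4.28 ± 0.170 (1.38, edgeR adjusted p = 0.00283). Of 72 oxidative phosphorylation genes 14 were higher with Dot1L and 2 with OGT, with a median of -0.32 (camera adjusted p = 0.00860). They included the cytochrome oxidase subunits COX6A1 (-1.23, edgeR adjusted p = 2.44e-05) and COX5B (-1.61, edgeR adjusted p = 3.21e-05) and the succinate dehydrogenase subunit SDHB (-1.43, edgeR adjusted p = 0.000207). Mitochondrial ribosomal protein genes, with 12 of 73 higher with Dot1L and 2 with OGT, missed the threshold (camera adjusted p = 0.0502). MRPS12 beside SARS2 (-1.06) and MRPS16 beside CFAP70 and DNAJC9 (-1.04) were higher with Dot1L and MRPS6 beside SLC5A3, which holds 6 Dot1L and 60 OGT fragments, with OGT (2.59). Without Dot1L replicate 2 the number of lists passing camera was 0, with 3 at an unadjusted p under 0.05.

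No other list passed camera, but several held genes that differed. Fry, which tests a list against no change and not against the other genes, also passed further lists, all toward Dot1L. These were mitochondrial ribosomal proteins and the proteasome (fry adjusted p = 0.0281 for both) and DNA replication (fry adjusted p = 0.0333). Of 29 OGT chromatin partners 3 were higher with OGT and 4 with Dot1L. HCFC1, the host cell factor that OGT binds and cleaves and whose window TMEM187 shares, had 21.7 ± 4.07 CPM with OGT and 12.3 ± 1.38 with Dot1L (0.83, edgeR adjusted p = 0.00624). KMT2E beside SRPK2 had 8.70 ± 3.44 and 22.3 ± 4.99 (-1.14, edgeR adjusted p = 0.000213). Of 31 genes of the list of DOT1L, the super elongation complex and partners 2 were higher with Dot1L. They were PAF1, a subunit of the polymerase-associated factor complex beside MED29 and SAMD4B (-1.17, edgeR adjusted p = 3.3e-05), and LARP7, which holds the 7SK particle and lies beside ZGRF1 (-0.90, edgeR adjusted p = 0.0185). Among 19 H2B ubiquitination genes 1 was higher with OGT, the deubiquitinase USP7, with 46 OGT and 3 Dot1L fragments, a ratio of 9.62 (95% counting interval 3.09 to 48.3). RNA splicing genes gave 7 of 47 higher with Dot1L and 0 with OGT, among them SNRPA beside ACTMAP (-0.93) and SNRPD2 beside QPCTL (-0.83), and proteasome genes 4 of 39 and 0, among them PSMD8 beside GGN (-1.16) and PSMA5 beside SORT1 (-0.78). Heat shock genes gave HSPA8 higher with Dot1L (-1.16) and BAG3 higher with OGT (1.64) within counts of 4 and 1 of 27. DNA replication genes split evenly, 3 and 3 of 46, with ORC6 beside VPS35 (-1.04) and MCM7 beside AP4M1 and COPS6 (-0.87) toward Dot1L and POLE beside P2RX2 and PXMP2 (1.57) toward OGT. Of 13 hexosamine pathway genes 1 was higher with Dot1L, NAGK (-0.94).

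Developmental genes also split. HOX genes gave 4 of 31 higher with Dot1L and 0 with OGT, among them HOXC6 beside HOXC4 and HOXC5 (-0.96) and HOXA10 beside HOXA11 and HOXA10-HOXA9 (-0.91). The developmental transcription factors often held by Polycomb gave 2 of 45 higher with Dot1L and 3 with OGT: OLIG2 (-1.20) was higher with Dot1L, and FOXA1 beside TTC6 (1.55) and EN2 (0.99) with OGT. Zinc finger genes, listed by ZNF symbol, gave 22 and 17 of 330, with ZNF524 beside FIZ1 (-1.01) toward Dot1L and ZNF696 (3.03) toward OGT. Histone genes (2 of 43, H3C4 and H2BC7, which share 1 window with H2AC7), mitosis genes (2 of 36, INCENP at -0.92 and CENPF at -0.77) and synthetase genes (2 of 18, with YARS1 beside NHSL3 and S100PBP at -0.58) were called toward Dot1L, and toward OGT 0, 0 and 1 (GARS1 at 0.95). Immediate early genes gave 1 of 24 toward OGT, FOSL1 beside CCDC85B (1.15), and p53 targets 1 each way of 17, FDXR (-0.77) and ZMAT3 (1.74). No call fell among 13 interferon genes, whose median of -0.11 lay below that of all genes although the test placed the list higher, or among the tested members of the olfactory (1), keratin (4), blood (1), liver (4), kidney tubule (2) and neuronal (4) lists. Adjusted over the list alone, the genes higher with OGT and with Dot1L were 1 and 19 for cytosolic ribosomal proteins, 2 and 15 for both mitochondrial lists, and 16 and 21 for zinc fingers. They were 0 and 3 for the proteasome, 1 and 5 for heat shock, 0 and 1 for mitosis, 2 and 2 for developmental factors and 0 and 1 for liver markers. In the other lists these counts equalled those adjusted over all genes. The DOT1L, OGT and OGA windows were not called: DOT1L, beside AP3D1, had 7.73 ± 0.410 CPM with OGT and 5.38 ± 0.489 with Dot1L, OGT 4.25 ± 0.471 and 5.77 ± 1.04, and OGA, the enzyme that removes O-GlcNAc, 24.3 ± 5.00 and 29.8 ± 3.06.

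The central comparison asks whether OGT on chromatin depends on Dot1L. CUT&Tag of OGT does not measure the amount of Dot1L, so the knockdown itself could not be checked. At the ends of the targeted gene, DOT1L (chromosome 19, 2163933 to 2232578; window shared with AP3D1), OGT stood at 28.9 and 23.4 CPM after control siRNA and 96.3 and 26.4 CPM after Dot1L siRNA (log2 difference 0.91, SE 0.606, edgeR adjusted p = 0.398). The gene OGT (chromosome X, 71533104 to 71575892) held 71 and 2 fragments, a ratio of 0.226 (95% counting interval 0.0268 to 0.847) with edgeR adjusted p = 0.163. OGA, beside NPM3, had 167 ± 15.0 CPM after control siRNA and 89.6 ± 13.2 after Dot1L siRNA (log2 difference -0.81, SE 0.331, edgeR adjusted p = 0.155), and HCFC1 134 ± 3.47 and 112 ± 46.2 (log2 difference -0.44, SE 0.344, edgeR adjusted p = 0.489). None of these 4 genes was called.

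After Dot1L siRNA the OGT level fell at 149 of 10857 tested gene ends and rose at 8, and 2107 had an unadjusted p under 0.05 (edgeR, scaled by total nuclear fragments). The whole distribution lay low, with a median log2 difference of -0.58, or -0.51 with the 500 genes without a Dot1L siRNA fragment set at their bound, and 77.9% of genes below 0. The falls named first are at genes with fragments left in both groups, though for UQCRH not in both Dot1L siRNA libraries. Over both Dot1L siRNA libraries together 3 fragments make 14.0 CPM, so these levels rest on few fragments, as do other called falls at similar levels. For UQCRH and SESN2 the SD after Dot1L siRNA was above the mean. UQCRH, a hinge subunit of complex III that shares its window with LRRC41, fell from 124 ± 12.1 to 26.4 ± 37.3 CPM (log2 difference -1.76, SE 0.461, edgeR adjusted p = 0.0257). HNRNPA2B1, an RNA-binding protein whose ends meet those of the heterochromatin gene CBX3, fell from 181 ± 12.7 to 66.9 ± 26.6 CPM (log2 difference -1.29, SE 0.349, edgeR adjusted p = 0.0309). RNF40, beside CFAP119 and PHKG2, fell from 168 ± 8.93 to 62.2 ± 42.6 CPM (log2 difference -1.19, SE 0.347, edgeR adjusted p = 0.0458). SESN2, a stress-induced regulator of growth signalling, fell from 82.5 ± 3.28 to 27.4 ± 29.4 CPM (log2 difference -2.12, SE 0.616, edgeR adjusted p = 0.0454).

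**Figure D3:**
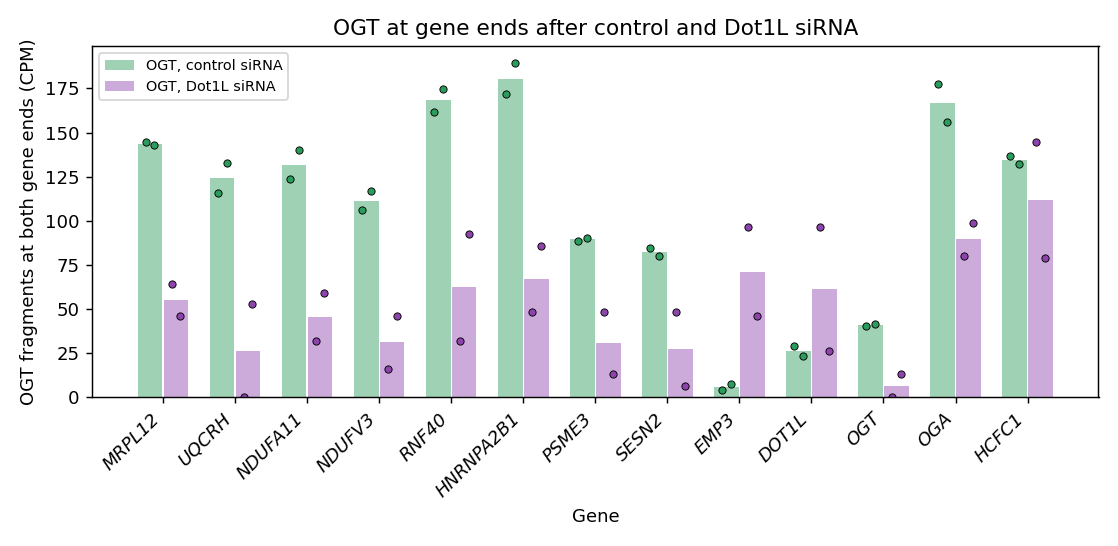
OGT fragments at both ends of 13 genes in CPM (vertical axis) after control siRNA and Dot1L siRNA; bars are means, points the 2 libraries of each group. MRPL12, UQCRH, NDUFA11, NDUFV3, RNF40, HNRNPA2B1, PSME3 and SESN2 fell, EMP3 rose, and DOT1L, OGT, OGA and HCFC1 were not called; with TMM scaling EMP3 alone of the 13 was called.

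The 10 largest falls were all at genes with no fragment in either Dot1L siRNA library, so only a bound can be given for each. POC5, a centriole protein, went from 54.3 ± 2.32 CPM to none and was at least 3.82-fold lower, CDK2AP2 (window shared with PITPNM1) at least 3.74-fold, PCYOX1 (shared with the splicing gene SNRPG) at least 3.70-fold, and TOMM40L (shared with NR1I3) at least 3.70-fold. FDXR, the mitochondrial ferredoxin reductase (shared with GRIN2C), was at least 3.62-fold lower, the protocadherin PCDH10 at least 3.41-fold, and the splicing factor BUD13 (shared with ZPR1) at least 3.20-fold. TENT5C was at least 3.16-fold lower, the clathrin adaptor subunit AP1S2 at least 3.12-fold, and the RNA-binding protein HNRNPR at least 2.99-fold. These genes had 72 to 92 fragments over both control siRNA libraries.

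Of the 8 rises 7 met the rule for naming. EMP3, an epithelial membrane protein gene (chromosome 19, 48325552 to 48330553), rose from 5.69 ± 2.59 to 71.2 ± 35.5 CPM (log2 difference 3.25, SE 0.692, edgeR adjusted p = 0.00698). The cargo receptor gene SURF4 (window shared with STKLD1 and SURF2) rose from 7.49 ± 2.41 to 61.3 ± 49.5 CPM (2.54, edgeR adjusted p = 0.0436) and ACBD4 (shared with PLCD3) from 11.6 ± 0.0893 to 52.3 ± 28.6 CPM (2.36, edgeR adjusted p = 0.0331). The others rest on 4 or 5 fragments: LAPTM5 and AKR1E2 had none after control siRNA and 4 after Dot1L siRNA, each at least 10.7-fold higher, and EVPL (shared with CDK3) and FAM78A had 1 and 5, each at a ratio of 40.1 (95% counting interval 4.49 to 1896). With TMM scaling, which takes out a log2 shift of -0.43 common to the gene ends, EMP3 was the 1 gene called and no fall passed the threshold, with 1034 at an unadjusted p under 0.05. The log2 differences of UQCRH, HNRNPA2B1, RNF40 and SESN2 were then -1.33, -0.86, -0.75 and -1.68. DESeq2 called 5 higher and 0 lower, with 731. TMM over 10 kb bins instead gave 6905 lower and 11 higher, with a median log2 difference of -1.64. The 157 calls were 45 without Dot1L siRNA replicate 1, 2 without Dot1L siRNA replicate 2, 37 without control siRNA replicate 1 and 31 without control siRNA replicate 2, while the median log2 difference was -0.55, -0.84, -0.50 and -0.47 in that order.

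No gene list moved apart from the other genes (camera, 26 lists, adjusted p under 0.05), with 8 at an unadjusted p under 0.05 and 0 with an estimated correlation. Without Dot1L siRNA replicate 1, control siRNA replicate 1 or control siRNA replicate 2 the number was 9, 8 or 7. The nearest were proteasome genes (median log2 difference -0.93, camera adjusted p = 0.0992), RNA splicing (-0.62), cytosolic ribosomal proteins (-0.56) and interferon response (-0.17, above the median of all genes), which had the same adjusted p. So did the blood cell list (2.56) with its 1 tested gene, TYROBP (window shared with HCST), which held 4 and 3 fragments. Summed over all 25 blood cell genes the level was instead 0.406 of that after control siRNA. That ratio is unsettled, since the control siRNA libraries differed widely (4.96 ± 5.08 CPM per gene, beside 2.02 ± 0.130 after Dot1L siRNA). For cytosolic ribosomal proteins the test pointed down while the median lay above the -0.58 of all genes. Fry, against no change, passed several lists, all pointing down, among them DOT1L with its partners and p53 targets (fry adjusted p = 0.00887 for both). With the whole distribution low, that does not set a list apart from the other genes. Of 39 proteasome genes 1 fell, PSME3, an activator of the nuclear proteasome beside AOC2, from 89.4 ± 1.08 to 30.7 ± 24.7 CPM (-1.93, edgeR adjusted p = 0.0492). Of 72 oxidative phosphorylation genes 3 fell, and 9 when adjusted over the list alone. The 3 were UQCRH and the complex I subunits NDUFA11 (shared with VMAC), from 132 ± 11.98 to 45.7 ± 19.3 CPM (-1.39, edgeR adjusted p = 0.0469), and NDUFV3 (shared with WDR4), from 112 ± 7.71 to 31.1 ± 21.3 (-1.60, edgeR adjusted p = 0.0486). Of 73 mitochondrial ribosomal protein genes 1 fell, MRPL12 (shared with HGS), from 144 ± 1.25 to 55.2 ± 12.8 CPM (-1.48, edgeR adjusted p = 0.0371). Of 47 splicing genes HNRNPA2B1 alone fell, of 19 H2B ubiquitination genes RNF40 alone, of 27 heat shock and unfolded protein genes SESN2 alone and of 17 p53 targets FDXR alone. LIG1, the replicative DNA ligase (shared with ZSWIM9), was the 1 of 46 replication genes to fall, with 108 and 2 fragments and a ratio of 0.148 (95% counting interval 0.0178 to 0.550). ZNF174 (shared with ZSCAN32) was the 1 of 330 zinc finger genes, with 154 and 3 fragments and a ratio of 0.156 (95% counting interval 0.0319 to 0.465).

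Adjusted over the list alone the falls were 5 for p53 targets, 3 for splicing, 3 for heat shock, 2 for the proteasome, 2 for H2B ubiquitination, 1 each for mitochondrial ribosomal proteins, replication, zinc fingers, mitosis, the hexosamine pathway, the DOT1L list and synthetases, beside the 9 for oxidative phosphorylation, and 0 in the others. Medians of lists with a called gene were -0.65 for oxidative phosphorylation, -0.49 for mitochondrial ribosomal proteins, -1.19 for H2B ubiquitination, -0.42 for replication, -0.60 for heat shock, -0.69 for p53 targets and -0.46 for zinc fingers. The remaining lists held no called gene. In these the medians were -0.56 for 31 genes of DOT1L, the super elongation complex and partners, -0.41 for 29 OGT chromatin partners, -0.95 for 13 hexosamine pathway genes, and -0.82 for 36 mitosis genes. They were -0.73 for 43 histone genes, -0.42 for 31 HOX genes, -0.69 for 45 developmental transcription factors, -0.81 for 24 immediate early genes and -0.31 for 18 synthetase genes. The median and the test differed in sign, relative to all genes, for mitochondrial ribosomal proteins, the DOT1L list, OGT chromatin partners and synthetases (median above, test lower) and for developmental factors and neuronal genes (median below, test higher). The few tested genes of other cell types had medians of 0.56 for 1 olfactory receptor, -0.21 for 4 keratins, -0.53 for 4 liver, -0.05 for 2 kidney tubule and -0.58 for 4 neuronal genes. With genes lacking a fragment at their bound, the liver median turned to 0.13, and the histone, HOX, developmental and immediate early medians were -0.63, -0.36, -0.55 and -0.77. Single values close to the threshold were those of the elongation factor SUPT6H beside PROCA1 and SDF2, at 121 ± 7.39 and 42.4 ± 14.6 CPM (-1.39, edgeR adjusted p = 0.0658), and the splicing factor SRSF2 beside METTL23 and MFSD11, at 172 ± 21.9 and 93.9 ± 48.8 (-1.13, edgeR adjusted p = 0.0541). Others were the mitotic activator CDC20 beside ELOVL1, at 81.2 ± 21.5 and 13.2 ± 18.6 (-2.03, edgeR adjusted p = 0.0585), and the ribosomal protein gene RPL26 beside KRABD2, with 121 and 3 fragments at a ratio of 0.199 (95% counting interval 0.0404 to 0.595). Summed over all listed members, tested or not, the level after Dot1L siRNA was 0.529 of that after control siRNA for p53 targets, 0.547 for H2B ubiquitination, 0.578 for the hexosamine pathway, 0.967 for interferon genes, 1.15 for olfactory receptors, 1.17 for keratins and 0.697 for all 20037 protein-coding genes.

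**Figure D4:**
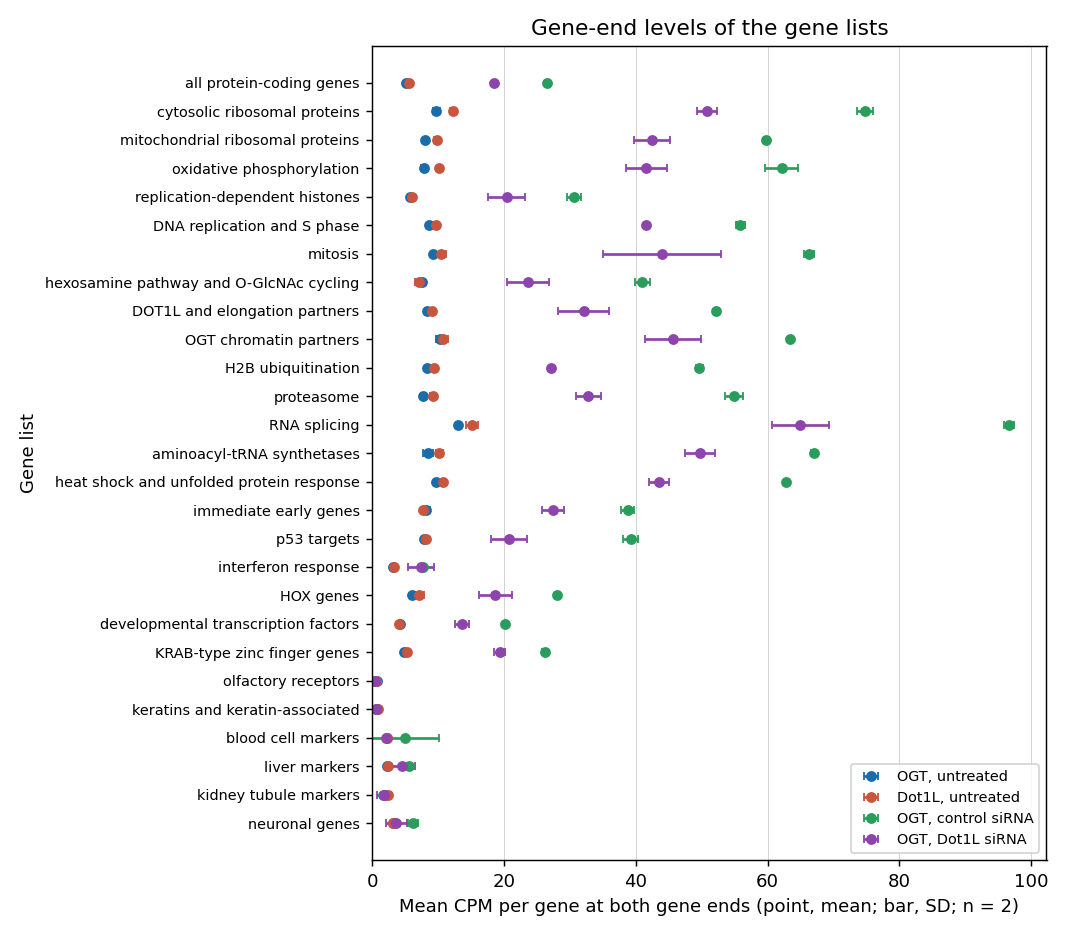
Mean CPM per gene over both gene ends (horizontal axis) of all protein-coding genes and the 26 gene lists (vertical axis) for OGT and Dot1L in untreated cells and OGT after control or Dot1L siRNA; points are means and bars SD of 2 libraries. RNA splicing genes stand highest after control siRNA at 96.7 and after Dot1L siRNA at 65.0, and olfactory receptor genes lie under 1 in all 4 groups.

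The design further asks whether the loss of OGT followed Dot1L. Of the tested genes 4518 overlapped a Dot1L region of untreated cells and 6339 did not. The fragments summed over the Dot1L-enriched genes had a Dot1L siRNA to control siRNA ratio of 0.670, from 0.661 to 0.678 over single libraries, against 0.722, from 0.721 to 0.724, over the others. The OGT level fell at 107 of the former and 42 of the latter. The Dot1L-enriched genes lay more often in the top quartile of untreated OGT level, where 82 of 2062 fell, against 13 of 651 others. In the other quartiles, from the lowest up, the falls were 1 of 372 against 2 of 2353, 6 of 774 against 14 of 1935, and 18 of 1310 against 13 of 1400. Over all tested genes the median log2 difference was -0.61 against -0.54, a gap of -0.07. With genes lacking a fragment at their bound it was -0.59 against -0.43, a gap of -0.17. Adjusted over this test and its 4 quartiles, camera passed with the preset correlation (adjusted p = 0.000173) and not with an estimated correlation (adjusted p = 0.227, unadjusted p = 0.0453). Within the top quartile of untreated OGT level the medians were -0.64 and -0.50 (camera adjusted p = 0.0153, and adjusted p = 0.273 with an estimated correlation). In the other 3 quartiles the test did not pass (camera adjusted p = 0.0624, 0.192 and 0.0624 from the lowest up). The ratio of summed fragments was lower at Dot1L-enriched genes in each quartile. From the lowest up it was 0.708 against 0.756, 0.693 against 0.709, 0.681 against 0.7235 and 0.658 against 0.705. Only in the quartile next to the lowest did the ranges over single libraries overlap. Without Dot1L siRNA replicate 2 the gap of the medians over all tested genes turned to 0.09, while without Dot1L siRNA replicate 1, control siRNA replicate 1 and control siRNA replicate 2 it was -0.19, -0.25 and -0.28.

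Inside genes, more than 1 kb from either end, the picture differed from that at the ends. Because CPM are shares, a lower share at gene ends must raise the share of the rest. Interiors held 37.3% of fragments after control siRNA and 41.2% after Dot1L siRNA, a ratio of 1.105. Outside both gene ends and interiors the share went from 19.3% to 28.3%, a ratio of 1.47, so the rise was not particular to interiors. The OGT level rose in 157 and fell in 18 of 13070 gene interiors after Dot1L siRNA, with a median log2 difference of 0.08 (edgeR). The genes that rose were long, with a median of 374 kb and 65.0% over 200 kb, against 44.6 kb and 9.86% for the genes not called and 32.2 kb for those that fell. The 8 with the smallest p in each direction, chosen after their values were seen, show this. CNTNAP2, a neurexin family gene of 2304 kb (chromosome 7, 146116801 to 148420998), rose from 168 ± 49.5 to 482 ± 45.9 CPM (edgeR adjusted p = 5.29e-12), the protocadherin PCDH9 from 531 ± 17.2 to 994 ± 21.0 CPM and the neuronal adaptor DAB1 from 226 ± 10.2 to 538 ± 33.6 CPM. PCDH15, ASIC2, RIMS1, CSMD1 and MARCHF1, all over 500 kb, rose by 1.15, 1.70, 1.89, 2.08 and 1.77 on the log2 scale. The Hedgehog receptor PTCH1 fell from 209 ± 17.4 to 73.1 ± 10.1 CPM (edgeR adjusted p = 0.00425), and the ubiquitin-conjugating enzyme UBE2D3 from 359.5 ± 39.5 to 179 ± 19.6 CPM (edgeR adjusted p = 0.00582). Falls also came at the corepressor SIN3A from 284 ± 11.8 to 174 ± 116 CPM, the protein kinase A subunit PRKAR1A from 189.8 ± 1.48 to 95.3 ± 69.5 CPM, GRSF1 from 121 ± 7.98 to 32.5 ± 0.611 CPM and GGPS1 from 282 ± 35.5 to 173 ± 95.6 CPM. The stress gene GADD45A had 157 and 3 interior fragments, a ratio of 0.153 (95% counting interval 0.0313 to 0.456), and KLF6, with 83 and 0, was at least 3.45-fold lower.

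Interior fragments summed by gene length gave a Dot1L siRNA to control siRNA ratio of 0.862 for the 2878 genes up to 20 kb, 0.967 for 4154 genes of 20 to 50 kb, and 1.02 for 2761 of 50 to 100 kb. It was 1.13 for 1904 of 100 to 200 kb, 1.305 for 1062 of 200 to 500 kb and 1.56 for 311 over 500 kb. Of the last class 62 rose and 0 fell. The ratio of untreated OGT to control siRNA also rose with gene length, from 0.391 in genes up to 20 kb to 2.70 in those over 500 kb. The count of 175 was 103 without Dot1L siRNA replicate 1, 14 without Dot1L siRNA replicate 2 and 31 without control siRNA replicate 2. The median log2 difference was 0.04, -0.31 and 0.12 in that order. TMM scaling turned the split of 157 and 18 to 22 higher and 194 lower, and TMM over 10 kb bins to 9 and 2184. DESeq2 gave 92 higher and 58 lower, with a median of -0.19.

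**Figure D5:**
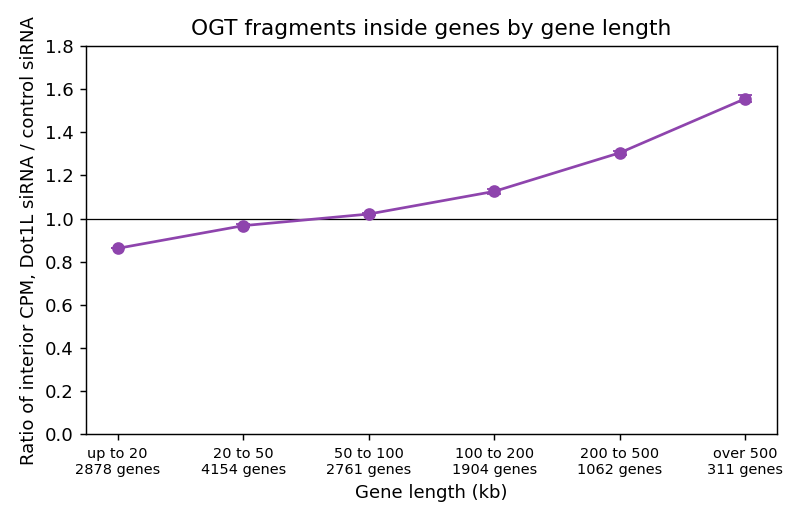
Ratio of summed interior OGT fragments in CPM, Dot1L siRNA over control siRNA (vertical axis, 1 marked), in 6 classes of gene length in kb (horizontal axis, with the number of genes). Points are ratios of group means and bars the range over the 4 pairings of single libraries; the ratio is 0.862 in the shortest and 1.56 in the longest genes.

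Of 5426 tested regions enriched for OGT in untreated cells, 44 fell after Dot1L siRNA and 0 rose, with a median log2 difference of -0.69, or -0.53 with empty regions at their bound, and 977 at an unadjusted p under 0.05 (edgeR). The 5 largest falls had no fragment in either Dot1L siRNA library. One lay on chromosome 5 at 80408001 to 80408500, inside ZFYVE16 at 391 bp from one end, with 98 control siRNA fragments and at least 4.07-fold lower. Another lay on chromosome 14 at 103562501 to 103563000, at an end of the co-chaperone gene BAG5, likewise with 98 fragments and at least 4.07-fold lower. The other 3, at least 3.53-fold lower each with 85 fragments, lay at an end of the RNA methyltransferase gene METTL16 (chromosome 17, 2511501 to 2512000), at FDXR (chromosome 17, 74872501 to 74874000) and at the neuronal kinase gene CDK5 (chromosome 7, 151057501 to 151058500). Whether a region is exonic or intronic could not be read from gene positions alone. TMM scaling and DESeq2 called 0 regions, with 548 and 338 at an unadjusted p under 0.05, and TMM over 10 kb bins 2911 lower and 0 higher, with a median of -1.76. Without Dot1L siRNA replicate 1, Dot1L siRNA replicate 2, control siRNA replicate 1 or control siRNA replicate 2 the count was 1, 0, 20 or 1 (546 at an unadjusted p under 0.05 where it was 0), and the median -0.73, -1.16, -0.68 or -0.62.

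The last comparison sets OGT after control siRNA against OGT in untreated cells, the same antibody without knockdown of Dot1L. The OGT level rose at 10170 of 10857 gene ends and fell at 13 (edgeR), with a median log2 difference of 2.46, while TMM scaling, which takes out a shift of 2.497, gave 1340 higher and 1719 lower and DESeq2 222 and 851. TMM over 10 kb bins gave 10396 higher and 6 lower. Per gene, RNA splicing genes went from 13.0 ± 0.203 to 96.7 ± 0.817 CPM, cytosolic ribosomal protein genes from 9.74 ± 0.463 to 74.8 ± 1.26. Aminoacyl-tRNA synthetase genes went from 8.43 ± 0.763 to 67.0 ± 0.466, oxidative phosphorylation genes from 7.84 ± 0.371 to 62.2 ± 2.495 and the proteasome from 7.66 ± 0.282 to 54.9 ± 1.352. Genes of other cell types had low values in both groups: olfactory receptors 0.678 ± 0.0292 and 0.291 ± 0.0505 CPM per gene, and keratins 0.782 ± 0.00540 and 0.496 ± 0.0949. Kidney tubule markers had 1.93 ± 0.00735 and 1.69 ± 0.171, liver markers 2.22 ± 0.217 and 5.52 ± 0.0424, neuronal genes 3.15 ± 0.197 and 6.14 ± 0.721, and blood cell markers 2.22 ± 0.266 and 4.96 ± 5.08. Interferon genes went from 3.16 ± 0.114 to 7.63 ± 0.184 and HOX genes from 6.04 ± 0.0641 to 28.0 ± 0.0864. Single genes show the same scale: EXOC8 had 34.0 CPM in untreated cells and 408 after control siRNA, MYL11 56.9 and 263, OGA 24.3 and 167, and HCFC1 21.7 and 134. The labels do not say whether the untreated and siRNA libraries were prepared together.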

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

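No test in this part was chosen after its result was seen. No group held the 4 libraries needed to test for a library far from the others. Mitochondrial fragments, which no comparison uses, made up 68.9% and 61.4% of the IgG libraries, 31.5% and 30.8% of the OGT libraries, 33.7% and 32.8% of the Dot1L libraries, 19.5% and 18.9% after control siRNA and 21.7% and 21.0% after Dot1L siRNA, so every antibody library lay below IgG.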

How the results depend on the processing

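Chosen after seeing the data were the gene end with more Dot1L fragments, each bin counted once in the gene tests, shares thinned to one depth with each bin counted once, the overlap without IgG bins and the estimated correlation for Dot1L-enriched genes. The 157 gene ends called after Dot1L siRNA became 1 with TMM, 6916 with TMM over 10 kb bins (6905 lower), and 5 with DESeq2. They became 78 with no filter, 80 with only the groups compared, 36 with 500 bp and 259 with 2.5 kb windows, 0 when thinned (edgeR, 1011 at an unadjusted p under 0.05, median log2 difference -0.51) and 0 with each bin counted once (1303, median turned to 1.15). Leaving out 1 library gave 2 to 45. The 175 interiors became 216 with TMM (22 higher, 194 lower), 2193 with TMM over 10 kb bins (9 higher), 58 with only the groups compared and 1 when thinned; leaving out 1 library gave 14 to 140. The 44 regions became 0 with TMM, 2911 with TMM over 10 kb bins (all lower), 0 with DESeq2, 94 with only the groups compared, 0 when thinned (501 at an unadjusted p under 0.05) and 22 with stricter regions; leaving out 1 library gave 0 to 20. The 1468 genes between OGT and Dot1L became 606 with TMM over 10 kb bins, 130 with DESeq2 and 387 when thinned; leaving out 1 library gave 228 to 924. The 10183 genes between control siRNA and untreated OGT became 3059 with TMM and 1073 with DESeq2; leaving out 1 library gave 9223 to 10091. Thinning removes fragments by construction, and otherwise the cause was not tested.

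The gap at Dot1L-enriched genes ranged from -0.284 to 0.0921 on leaving out 1 library, reversed without Dot1L siRNA replicate 2. The number of lists passing ranged from 0 to 9 after Dot1L siRNA and from 0 to 3 between antibodies, where an estimated correlation gave 0 (camera, 2 at an unadjusted p under 0.05). The overlap of OGT with Dot1L regions ranged from 19.2% to 69.9% on leaving out 1 library. The gene-end share ratio of Dot1L siRNA to control siRNA was 0.686 with 500 bp and 0.734 with 2.5 kb windows, 1.645 with each bin counted once and 0.732 when also thinned, and 0.697 to 0.705 on leaving out 1 library. OGT over Dot1L was 0.852 with each bin counted once and 0.940 to 0.952 on leaving out 1 library. Control siRNA over untreated OGT was 5.22, 3.99, 3.48 and 4.12 for the same 4 settings, and 4.89 to 4.95 on leaving out 1 library. OGT over IgG was 0.771, 0.810, 0.350 and 0.725, and 0.733 to 0.762. With each bin counted once, where deeper libraries fill their bins by construction, the log2 difference turned positive at MRPL12 (0.57), UQCRH (0.42), NDUFA11 (0.99), NDUFV3 (0.83), RNF40 (0.84), PSME3 (1.155), HNRNPA2B1 (1.98), SESN2 (0.57) and ZNF174 (0.57).

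The replicate numbers, with 2 pairs, do not establish a pairing. Replicate 2 was 2.31 to 2.43 times as deep as replicate 1 in every antibody group, and whether the number marks a shared run was not tested. With the replicate block the counts were 139, 130, 34, 1309 and 10144 in the order above, the gap was -0.0731, and 0 and 3 lists passed (camera, 7 and 3 at an unadjusted p under 0.05). Of 27 named genes called after Dot1L siRNA, 1 was called with TMM, 3 with DESeq2, 23 with the block and 0 without Dot1L siRNA replicate 2; of 67 named between antibodies, 66, 13 of 49 with a value, and 64 were called with TMM, DESeq2 and the block.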

Other observations

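Every test in this part was chosen after the result was seen. The bins with the most OGT and Dot1L fragments in untreated cells lay at nuclear copies of mitochondrial genes. A named copy lay in 7 of the 10 highest OGT bins, 6 of the 10 highest Dot1L bins and 0 of the 10 highest in either siRNA group. The bins without a gene name among the highest OGT and Dot1L bins lay near the named copies MTRNR2L1 (chromosome 17, 22523001 to 22523500) and MTRNR2L8 (chromosome 11, 10508001 to 10508500). The counts by name may therefore be too low. The pseudogene MTCO1P40 (chromosome 17, 53106001 to 53106500) was highest in both, at 89.0 ± 23.4 CPM with OGT and 107.7 ± 9.96 with Dot1L, beside 1138 ± 211 with IgG (2 and 5 fragments), 40.2 ± 10.5 after control siRNA and 63.2 ± 24.1 after Dot1L siRNA (SD, n = 2). MTCO1P53 (chromosome X, 126472001 to 126472500) had 87.0 ± 22.3 CPM with OGT, 99.4 ± 36.4 with Dot1L and 841 ± 631 with IgG (2 and 2 fragments). MTCO3P12 (chromosome 1, 634501 to 635000) had 77.3 ± 16.8 and 87.7 ± 12.8 CPM, and 0 and 1 IgG fragments, below the IgG floor of 453.6 CPM. The highest bin in both siRNA groups (chromosome 1, 231338001 to 231338500) lay at SPRTN, beside EXOC8, at 182.7 ± 11.5 CPM after control siRNA and 121 ± 80.5 after Dot1L siRNA. Reads from the mitochondrial genome may be shared with such copies, and their share was not tested; the 10 highest bins hold at most 0.13% of the fragments of an antibody library.

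The gene-end share of OGT fragments was lower after Dot1L siRNA than after control siRNA. Lower depth or repeated fragments as the whole cause are argued against by a ratio of 0.732 at one depth with each bin counted once, where 0.9 or more would be needed. A fall of the share confined to gene ends with a called Dot1L region is argued against by a ratio of 0.722 at gene ends without one. More background would also lower that ratio, so whether a loss of OGT itself was confined to the called gene ends is not decided by it. A region had to be called in both libraries at their depth, so gene ends without one may still hold Dot1L. A loss confined to all gene ends that hold Dot1L is therefore not addressed by this value. More background of the kind in the untreated libraries cannot be told apart. A mixture with 37.5% of the untreated profile gave the interior ratio in 6 gene length classes with a largest deviation of 11.7%, past the 10% set for it. The ratio under 1 in genes over 500 kb that would exclude such background was not seen. That limit was set after the ratio of 1.56 there had been seen, so its outcome carries no weight. An effect of Dot1L siRNA on OGT is the hypothesis the design names and remains open, as does a lower yield in those libraries.

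The gene-end share was also higher after control siRNA than in untreated cells, with no Dot1L siRNA in either. Depth or repeated fragments as the whole cause are argued against by a ratio of 4.12 at one depth with each bin counted once. A few bins taking most fragments are argued against by the share of the 10 highest bins. It was 0.122% and 0.119% after control siRNA and 0.0381% and 0.0562% in the untreated OGT libraries. The labels name no batch, so a difference in preparation was not tested, nor was an effect of the control siRNA treatment.

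The 2 libraries of each antibody group shared single-fragment bins more often than neighbouring bins, by a factor of 1.28 for OGT, 2.05 for Dot1L, 1.15 after control siRNA and 2.74 after Dot1L siRNA. Sites that every library favours are argued against by a highest ratio of 1.05 between antibody groups, and narrow sites of the OGT antibody by a highest ratio of 1.04 across the OGT groups. Whether some fragments are the same in both libraries of a group cannot be told. The lowest ratio within an antibody group, 1.147, lay above every ratio between antibody groups. It lay below 5 of the 16 pairs with an IgG library, the highest at 1.81, but pairs with IgG rest on only 1030 or 2903 single-fragment bins. Replicate 2 was 2.39, 2.42, 2.31 and 2.43 times as deep as replicate 1 for OGT, Dot1L, control siRNA and Dot1L siRNA, and 3.26 times for IgG. Whether the 2 libraries of a group are runs of the same material thus remains open. Sites favoured by IgG and by both siRNA groups are argued against, for the siRNA groups, by ratios of 0.992 to 1.04 between the control and Dot1L siRNA libraries. Sites that IgG shares with a single siRNA group remain open. No biological explanation other than such sites was tested.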
